A study of Homo sapiens with 8 samples.

How the data were processed

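The series holds 8 single-colour arrays of CAL-27 cells: 3 controls, 3 treated with enzastaurin and 2 treated with Go, each hybridised with Cy3-labelled total RNA per the labels. The groups and replicate numbers are those of the labels, and the dose of Go is not given there. Protein kinase C appears in the series title as PCK.

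The scanner tables are GenePix result files, per the file headers, and give for each spot the pixel mean and median intensity of foreground and background, neither background-corrected nor normalised. The same deposited tables give the signal-to-noise score and the percent of saturated pixels of each spot, and other columns give spot positions in µm. The channel is named in the headers for a longer wavelength than that of the dye in the labels; only 1 channel was recorded. A deposited table of values per sample holds, by comparison with the scanner tables, the authors' background-subtracted intensity on a linear scale with a floor of 0.5 and no normalisation, with sample medians of 38 to 56.

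The annotation in the scanner tables runs end for end against the spots on all 8 arrays. As deposited, replicate spots of a probe differed with an SD of 3.62 to 4.06 on the log2 scale, and the rank correlation with the authors' value table was 0.0039 to 0.0092 across probes. With the annotation rotated, the SD was 0.283 to 0.404, the correlation 0.99 to 0.9935, and 39.7% to 42.2% of values were exactly equal. The rotated annotation was used. Correlations across probes are descriptive, since probes are not independent replicates.

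The design, gene lists, alternatives and the rule for naming genes were set before the data were examined, for files from another scanner program. The files are GenePix tables, and 3 things differ from that design. Of these, the normalisation was a choice, since scaling to the 75th percentile can also be done with such files. Foreground mean and background median were corrected with normexp (offset 50) and quantile normalised between arrays, in place of a processed signal scaled to the 75th percentile. A probe counted as above background where the signal-to-noise score exceeded 3, and was tested if this held on at least 2 arrays; at most 0.654% of 153 negative control spots exceeded that score on an array. The files mark no outlier spots, only spots not found (25.5% to 31.4% of spots), so the planned setting that keeps outlier spots was not run.

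Of 41000 probes 27538 received a gene symbol: 23434 by RefSeq accession, 2317 by current symbol, 1038 by a unique older symbol and 749 by the name in the file only. The reference table belongs to GRCh38.p14 and was used only for names, so no coordinates are given. The 13462 other probes were kept apart. The named probes covered 18093 symbols. Spots of a probe were averaged, and the probe with the highest mean stood for its gene, which left 12910 genes.

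Genes were tested with limma's moderated t statistic in a fit with the 3 groups (residual degrees of freedom 5, prior 3.7), with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are log2 differences with standard errors, and intervals are 95%. A probe not above background on any array of a group gives only a lower bound of the fold, for which each array's value is raised to the lowest value of any probe above background on it, if smaller. Gene lists were tested with camera at a preset correlation of 0.01, with camera and an estimated correlation, and with fry. Of 29 lists 28 had at least 5 measured members. The endothelial list had 4 and was not tested. A count described as adjusted over the list alone uses adjustment within that list.

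The slide of each array is not in the labels. It was inferred from mean horizontal spot positions, 10930.1 to 10951 µm for control 1, 2, 3 and Go 1 and 10897.1 to 10904.5 µm for Go 2 and enzastaurin 1, 2, 3. A fit with the slide as a block (residual degrees of freedom 4, prior 3.85) is reported beside the other.

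Named genes are, for each comparison, the 10 largest rises and 10 largest falls among genes called, above background on every array of at least 1 group, and with groups that do not overlap; up to 4 called members of each list; and CYP1A1, CYP1B1, PRKCA, PRKCB, EGFR, CCND1, VEGFA, MKI67 and IVL in any case. From these the text takes those that held in most settings, a choice made after the values were seen. Values of some list members are not reported here.

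The gene test was tested on simulated data, with 200 of 12910 genes changed in each of 10 runs. For a log2 change of 2, 1 and 0.5 it recovered 98.8%, 93.1% and 53.5% for enzastaurin against control, 98.5%, 86.1% and 43% for Go against control, and 98.1%, 87.2% and 44.2% for Go against enzastaurin. False calls made up 5.15%, 4.28% and 4.07% of the calls. The simulated noise was independent for each gene and array, with no slide difference and no array difference shared by genes. These shares therefore check the procedure and do not give the rate of false calls on the real arrays.

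Alternatives chosen in advance were the filter on dim probes, the values the authors deposited, the mean of all probes of a gene, only the groups compared, an intensity trend, array weights, the replicate number or slide as a block, each array left out, and a fold threshold. Alternatives added after seeing the data were median scaling, plain background subtraction, pixel medians, spots not found left out and tests within a slide. The position of each array along the difference between control 1 and control 3 was added then as a covariate. Scaling to the 75th percentile was the design's normalisation, but was run as an alternative only after seeing the data. R 4.3.3, limma 3.58.1, the data.table package at version 1.17.8, Python 3.11.15 and matplotlib 3.10.9 were used.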

Results

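Gene expression was measured in CAL-27 cells, a human squamous carcinoma line of the head and neck, after serum starvation and 24 h of exposure to an inhibitor of protein kinase C. The groups compared on 8 single-colour arrays were untreated control (n = 3), enzastaurin at 10 µM (n = 3) and a compound that the labels call Go (n = 2), whose dose is not stated. Each array held 45220 spots, with median foreground intensities of 75 to 99 and a 75th percentile of 285 to 519. Between 52.1% and 57.3% of the probes lay above background on an array, and 14 to 53 probes were saturated. The tests covered 12910 genes. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these arrays.

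The arrays did not separate by treatment alone. Spot positions place control 1, 2 and 3 and Go 1 on a first slide, and Go 2 and the enzastaurin arrays on a second. The first principal component held 76.4% of the variance, with the controls at -48.5, -40.9 and -21, Go 1 at 0.2, Go 2 at 22.8 and enzastaurin at 27.6, 28.9 and 30.9. The root mean square log2 difference between control 1 and control 3 was 0.351, the same as between Go 1 and Go 2, while pairs of enzastaurin arrays differed by 0.119 to 0.162. Enzastaurin and control therefore share no slide, and every difference between them is also a difference between slides. Counts of genes called are given with and without the slide as a block.

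**Figure D1:**
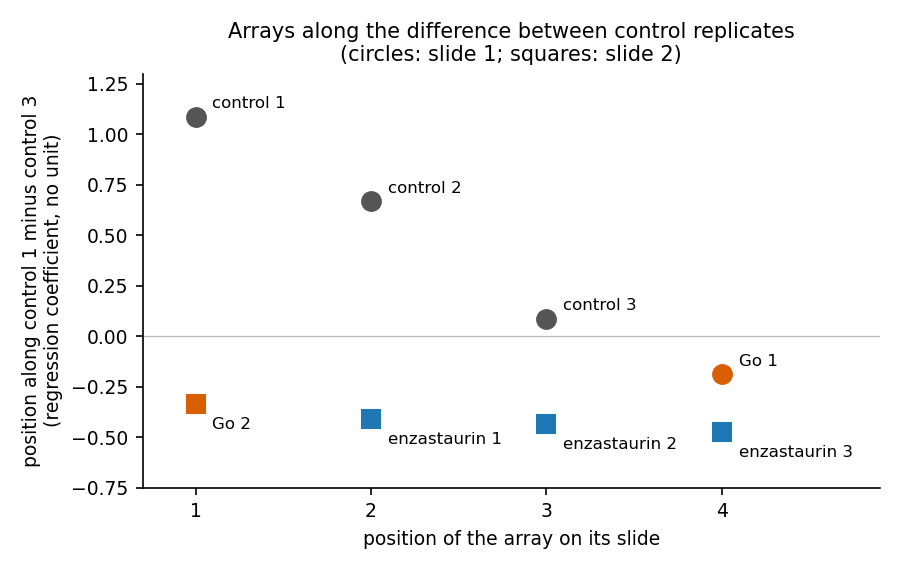
Each point is an array, with its position on its slide on the horizontal axis and its position along the difference of control 1 from control 3 (regression coefficient, no unit) on the vertical axis; colours give control (n = 3), enzastaurin (n = 3) and Go (n = 2), circles slide 1 and squares slide 2. The controls lie at 1.087, 0.667 and 0.087, Go 1 at -0.189, and the arrays of slide 2 between -0.337 and -0.473.

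The comparison of Go with enzastaurin asks where the 2 inhibitors differ, and Go is the group present on each slide. Relative to enzastaurin (n = 3), PI3, the secreted elastase inhibitor elafin, was higher in Go (n = 2) by 2.09 on the log2 scale (SE 0.204, limma adjusted p = 0.00163). CYP1A1, a xenobiotic-metabolising enzyme induced through the aryl hydrocarbon receptor, was at least 3.26-fold higher (adjusted p = 5e-04), a lower bound because no enzastaurin array was above background for it. MMP7 and MMP1, secreted proteases that degrade extracellular matrix, fell by 1.55 on the log2 scale (SE 0.093, adjusted p = 0.000298) and decreased by 1.37 (SE 0.14, adjusted p = 0.00167). In all, 1054 of 12910 genes passed an adjusted p of 0.05 (633 higher and 421 lower in Go), 52 of them by at least 2-fold (34 higher, 18 lower).

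Other large rises in Go over enzastaurin were in JDP2, a repressor of AP-1 (1.60, SE 0.112), PDZK1, a scaffold protein (1.56, SE 0.085), DHRS2, a short-chain dehydrogenase (1.51, SE 0.115), PIP (1.49, SE 0.19), ADA2 (1.47, SE 0.232), the protease KLK10 (1.46, SE 0.159) and OLFM4 (1.45, SE 0.149). The largest falls included the metalloprotease TLL2 (-1.75, SE 0.089), ZBED2 (-1.58, SE 0.18), the melanosomal and lysosomal glycoprotein GPNMB (-1.32, SE 0.1), the receptor CSF1R (-1.31, SE 0.095), LYRM1 (-1.24, SE 0.127) and LPCAT1, an acyltransferase of phospholipid remodelling (-1.18, SE 0.119). DEFB103B, a beta-defensin with a near-identical copy that makes its name uncertain, was at least 2.46-fold lower. Adjusted p-values of these genes lay between 0.000193 for PDZK1 and TLL2 and 0.00907 for ADA2. The arrays of the groups did not overlap in 48% of all genes, against 20% by chance.

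**Figure D2:**
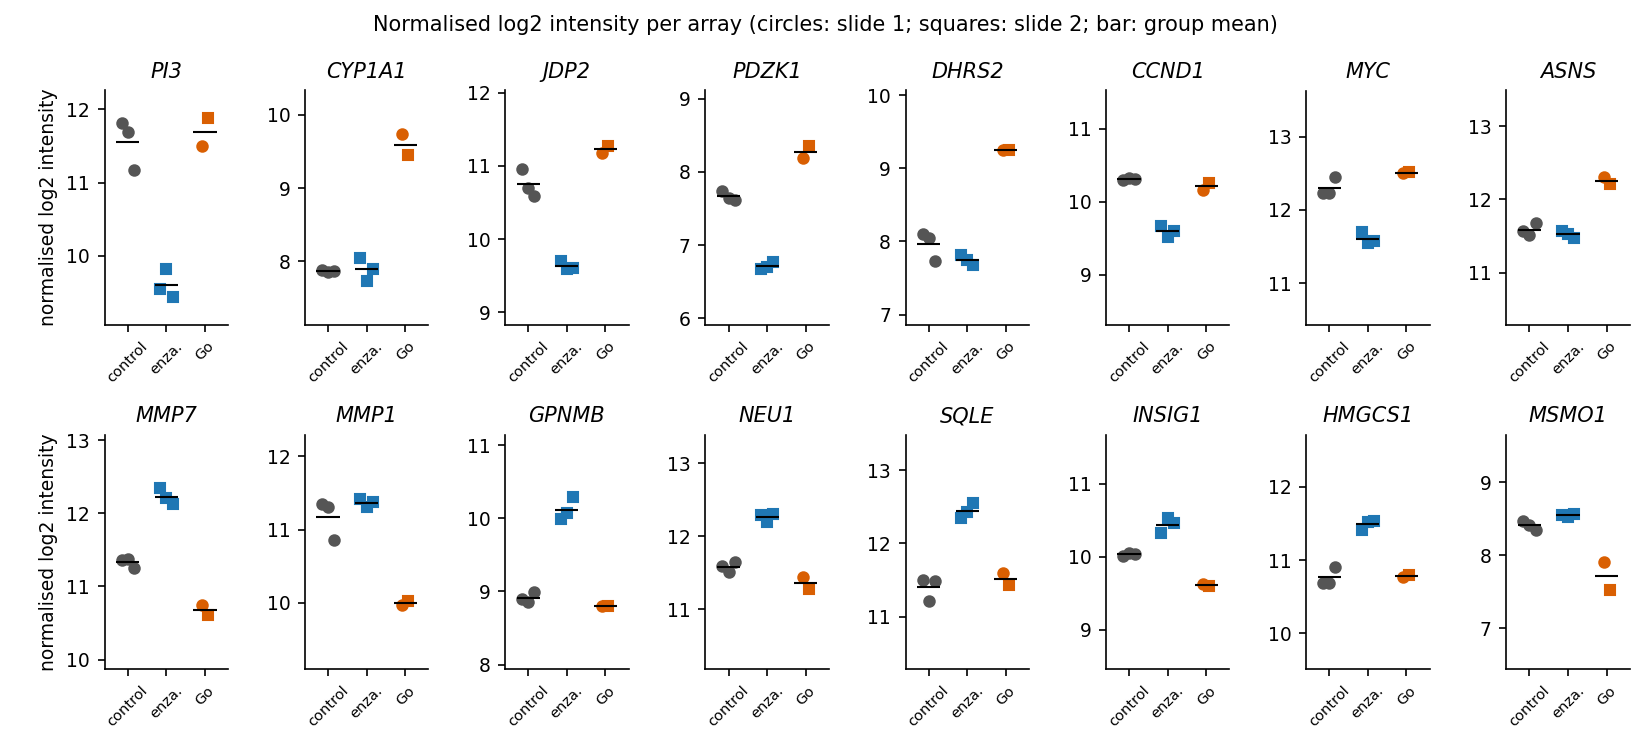
Normalised log2 intensity of 16 genes on each of the 8 arrays, grouped as control (n = 3), enzastaurin (n = 3) and Go (n = 2), with circles for slide 1, squares for slide 2 and the same log2 range in every panel. CYP1A1 is higher in Go (at least 3.26-fold over enzastaurin), while GPNMB and MMP7 are lower in Go than in enzastaurin by -1.32 and -1.55.

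Genes of cholesterol synthesis were lower in Go than in enzastaurin as a group. Of 25 measured members, 10 fell, 0 rose and 15 did not pass (15 fell adjusted over the list alone), with a median of -0.47. The falls included the squalene epoxidase SQLE (-0.93, SE 0.115, adjusted p = 0.00325), the sterol sensor INSIG1 (SE 0.084, adjusted p = 0.00167), which decreased by 0.82 on the log2 scale, and the methylsterol oxidase MSMO1 (at least 1.77-fold lower, since Go was not above background). The list passed the camera test (adjusted p = 5.15e-12; adjusted p = 0.0541 with an estimated correlation). Lysosome and autophagy genes were lower as well: of 23, 6 fell, 1 rose and 16 did not pass (9 fell and 1 rose adjusted over the list alone), among them GPNMB and the sialidase NEU1 (-0.90, SE 0.088). That list's adjusted p was 1.85e-05 (adjusted p = 0.116 with an estimated correlation).

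Targets of ATF4, the transcription factor of the amino acid response, were higher in Go. Of 24 members 7 rose, 1 fell and 16 did not pass (13 rose and 1 fell adjusted over the list alone), with a median of 0.40. The subunits of the large neutral amino acid transporter, SLC7A5 (0.79, SE 0.103) and SLC3A2 (0.79, SE 0.08), and asparagine synthetase, ASNS (0.73, SE 0.083), were among them. The list's adjusted p was 8.25e-05 (adjusted p = 0.226 with an estimated correlation). Targets of YAP and TAZ were also higher: of 19, 6 rose and 13 did not pass (8 rose adjusted over the list alone). The rises included ARHGEF17 (0.86, SE 0.082), the Hippo kinase LATS2 (0.72, SE 0.096) and IGFBP3 (0.67, SE 0.092). The IGFBP3 call was lost with the mean of its probes, at a log2 change of 0.59. Its limma adjusted p ran from 0.00417 to 0.056 over all alternatives. The adjusted p of the YAP and TAZ list was 0.000487 (adjusted p = 0.226 with an estimated correlation).

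**Figure D3:**
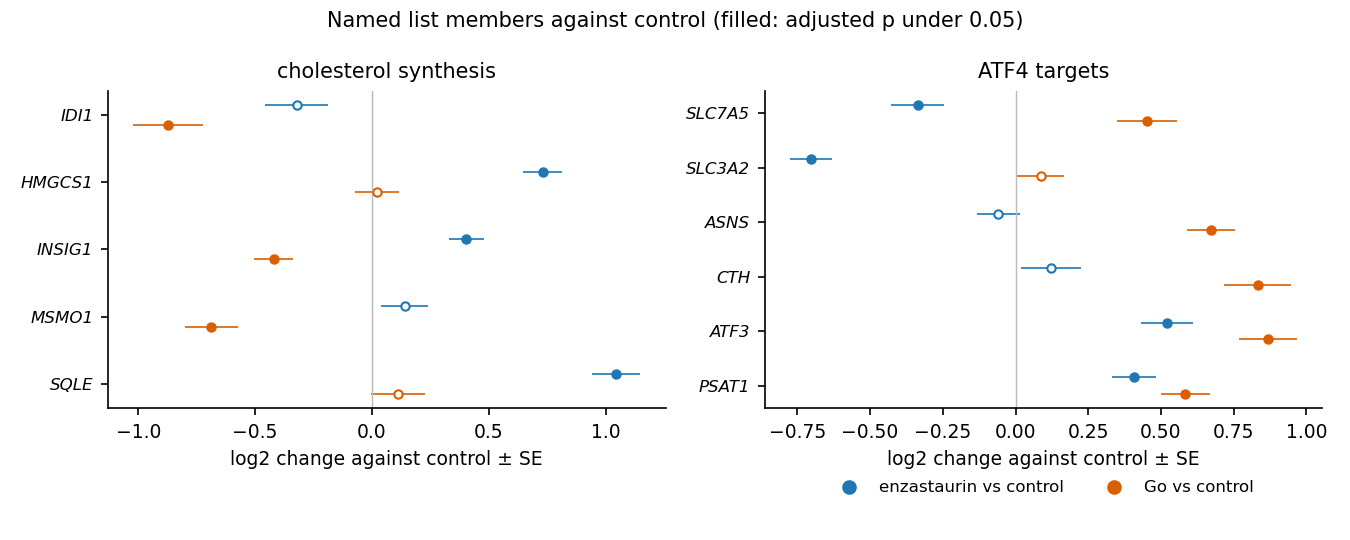
Log2 change against control (points, with SE) of members of the cholesterol synthesis and ATF4 lists that the text names, for enzastaurin (n = 3) and Go (n = 2), with filled points for genes called. For SQLE the change was 1.04 in enzastaurin, and the difference between Go and enzastaurin was -0.93; for ASNS it was 0.67 in Go, and the difference was 0.73.

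Matrix proteases and the plasminogen system were lower in Go than in enzastaurin: of 18 members, 7 fell, 1 rose and 10 did not pass (9 fell and 4 rose adjusted over the list alone). Besides MMP7 and MMP1, the protease inhibitor SERPINE2 fell (-0.94, SE 0.084). The adjusted p was 0.000855 (adjusted p = 0.226 with an estimated correlation). Among hypoxia and glycolysis genes 4 of 22 fell and 18 did not pass, the same adjusted over the list alone, with EGLN3, an oxygen-sensing prolyl hydroxylase, at -1.01 (SE 0.164; adjusted p = 0.0104, 0.0514 without enzastaurin 1 and 0.00244 to 0.0514 over all alternatives). That list's adjusted p was 0.0016 (adjusted p = 0.234 with an estimated correlation). Basal keratinocyte and hemidesmosome genes had a median of -0.24 and an adjusted p of 0.000758 (adjusted p = 0.116 with an estimated correlation), but only COL17A1 fell by itself of 18 measured, also adjusted over the list alone (-0.50, SE 0.11). That call, adjusted p = 0.0304, was lost without enzastaurin 1 (0.107), enzastaurin 2 (0.068), enzastaurin 3 (0.102) or Go 1 (0.0869), with a range of 0.00865 to 0.107 over all alternatives.

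Of 25 interferon response genes 4 rose and 21 did not pass (6 rose adjusted over the list alone), including OASL (0.96, SE 0.125) and IFIT2 (0.85, SE 0.118). Their adjusted p was 0.00181 (adjusted p = 0.617 with an estimated correlation), 0.0662 without Go 1, and 9.19e-05 to 0.0662 over the alternatives with the preset correlation. Aryl hydrocarbon receptor targets passed with CYP1A1 alone called among 9 (3 rose adjusted over the list alone; adjusted p = 0.0288, and adjusted p = 0.226 with an estimated correlation). Without Go 1 that list's adjusted p was 0.124, and over the same alternatives it ran from 0.00984 to 0.143. Mesenchymal genes passed with 5 falls among 13 and 8 not past, the same adjusted over the list alone, such as the matrix protein TNC (-0.82, SE 0.122). The list had an adjusted p of 0.0393 (adjusted p = 0.226 with an estimated correlation), 0.124 without Go 1 and 0.0728 without Go 2, in a range of 0.0135 to 0.124. Ribosomal protein genes had a median of -0.07 with 1 fall (RPL4, -0.28, SE 0.072) among 28 and 0 adjusted over the list alone (adjusted p = 0.0393; adjusted p = 0.44 with an estimated correlation). The list's call was lost without Go 1 (0.125) and without enzastaurin 2 (0.175), and the range was 0.0138 to 0.51, the highest with arrays scaled to the 75th percentile. RPL4 itself was not called without Go 1 (0.0895), Go 2 (0.0691), control 2 (0.0938) or enzastaurin 1, 2 or 3 (0.163, 0.146 and 0.136), in a range of 0.0251 to 0.163.

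Single members changed in lists that did not pass. MYC rose by 0.90 (SE 0.095, adjusted p = 0.00182), the ERK phosphatase DUSP6 by 0.80 (SE 0.113, adjusted p = 0.00587), the transcription factor KLF2 by 0.77 (SE 0.089) and CCND1, cyclin D1, by 0.61 (SE 0.081, adjusted p = 0.00423, with 3 of its 3 probes called). The ERK output list had 6 rises among 19 and 13 not past (6 rises and 2 falls adjusted over the list alone), an adjusted p of 0.508, and a median of -0.01 against a mean of 0.14. The cell cycle inhibitor CDKN1A (-0.64, SE 0.092), the reductase AKR1C1 (-0.82, SE 0.122), SOD2 (-0.60, SE 0.092) and the cornified envelope precursor SPRR1A (-0.97, SE 0.162) fell, while KRT4 rose (1.11, SE 0.13). NRF2 targets had 5 falls among 19 and 14 not past (5 falls and 1 rise adjusted over the list alone; adjusted p = 0.131), with a median of 0.02 against a mean of -0.09. None of the 35 DNA replication genes passed (adjusted p = 0.845), nor any of the 14 BCL2 family genes (0.59), the 12 protein kinase C and D genes (0.563; 2 falls adjusted over the list alone) or the 13 FOXO targets (0.781). CYP1B1 differed by 0.50 (SE 0.147, 95% interval 0.17 to 0.84, adjusted p = 0.0717) and PRKCA, protein kinase C alpha, by -0.31 (interval -0.50 to -0.12, adjusted p = 0.0581). EGFR differed by 0.27 (-0.12 to 0.65), IVL by 0.13 (-0.17 to 0.43), VEGFA by -0.39 (-0.70 to -0.07) and MKI67 by -0.10 (adjusted p = 0.537). None of these passed the test, and PRKCB did not reach the level needed for it. Some passed in a limma fit without 1 array: CYP1B1 without control 1 (0.039) or control 3 (0.0385), PRKCA without control 1 (0.0463) or control 3 (0.0484), EGFR without Go 2 (0.00901) and VEGFA without Go 1 (0.0247). Over all alternatives the adjusted p ran from 0.0103 to 0.223 for CYP1B1, 0.034 to 0.27 for PRKCA, 0.00901 to 0.802 for EGFR and 0.0247 to 0.427 for VEGFA.

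The remaining lists did not pass either in the setting used. Immediate early genes had 4 rises among 19 (7 rises and 2 falls adjusted over the list alone; adjusted p = 0.461), and NF-kB genes 4 rises and 3 falls among 27 (8 and 5 adjusted over the list alone; adjusted p = 0.781). Wnt targets had 3 rises, MYC and CCND1 among them, and 1 fall, TCF7 (-0.59, SE 0.081), among 11 (3 and 2 adjusted over the list alone; adjusted p = 0.782). Unfolded protein response genes had 2 rises and 1 fall among 14 (0.781), terminal differentiation genes 1 rise and 1 fall among 25 (0.781), p53 targets 1 and 1 among 20 (2 and 2 adjusted over the list alone; 0.363), and ErbB genes 1 rise among 10 (ERBB2, 0.59, SE 0.108; list 0.29). Heat shock genes had 1 fall among 10 (HSPE1, -0.70, SE 0.126; 2 falls adjusted over the list alone; list 0.0647) and mitosis genes 1 rise among 32 (KIF20A, 0.39, SE 0.094; 0 adjusted over the list alone; list 0.156). Each of these 2 lists passed without enzastaurin 1 (0.0388). Heat shock genes also passed without the filter on dim probes and with the mean of a gene's probes, in 3 alternatives in all (0.0306 to 0.0426), and mitosis genes with replicates as a block, in 2 in all (0.0231 and 0.0388). With an estimated correlation the adjusted p was 0.226 for heat shock and 0.79 for mitosis. Markers of cells other than keratinocytes were measured too: of 5 fibroblast markers 1 fell (LUM, adjusted p = 0.984 for the list), and of 6 leukocyte markers 1 fell (HLA-DRA, adjusted p = 0.842 for the list). These single calls were lost in limma fits without enzastaurin 1, 2 or 3, where adjusted p was 0.0639, 0.0732 and 0.062 for ERBB2, 0.0708, 0.067 and 0.0515 for HSPE1, 0.0749, 0.147 and 0.119 for KIF20A, 0.107, 0.0997 and 0.112 for LUM, and 0.149, 0.115 and 0.121 for HLA-DRA. KIF20A, LUM and HLA-DRA were lost as well without control 2 (0.0785, 0.0626 and 0.0853) or Go 1 (0.121, 0.103 and 0.0963), and HLA-DRA without control 1 (0.054). Over all alternatives the ranges were 0.00695 to 0.0732 for ERBB2, 0.00134 to 0.209 for HSPE1, 0.0267 to 0.215 for KIF20A, 0.0196 to 0.149 for LUM and 0.00178 to 0.149 for HLA-DRA.

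Within the slide block, which is Go 2 alone against the enzastaurin arrays, the same fit as without Go 1, 1001 genes passed and 600 of the 1054 were among them; the lone array is assumed to vary like those of the other groups. The count moved to 264, 246 or 383 without enzastaurin 1, 2 or 3, to 514 without control 2 and to 1706 without Go 2; 43 of the 79 named genes called here kept their call in each of these fits. The share of calls that were higher in Go was 60.1%, and 31.9% (261 of 818) when arrays were scaled to their median.

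**Figure D4:**
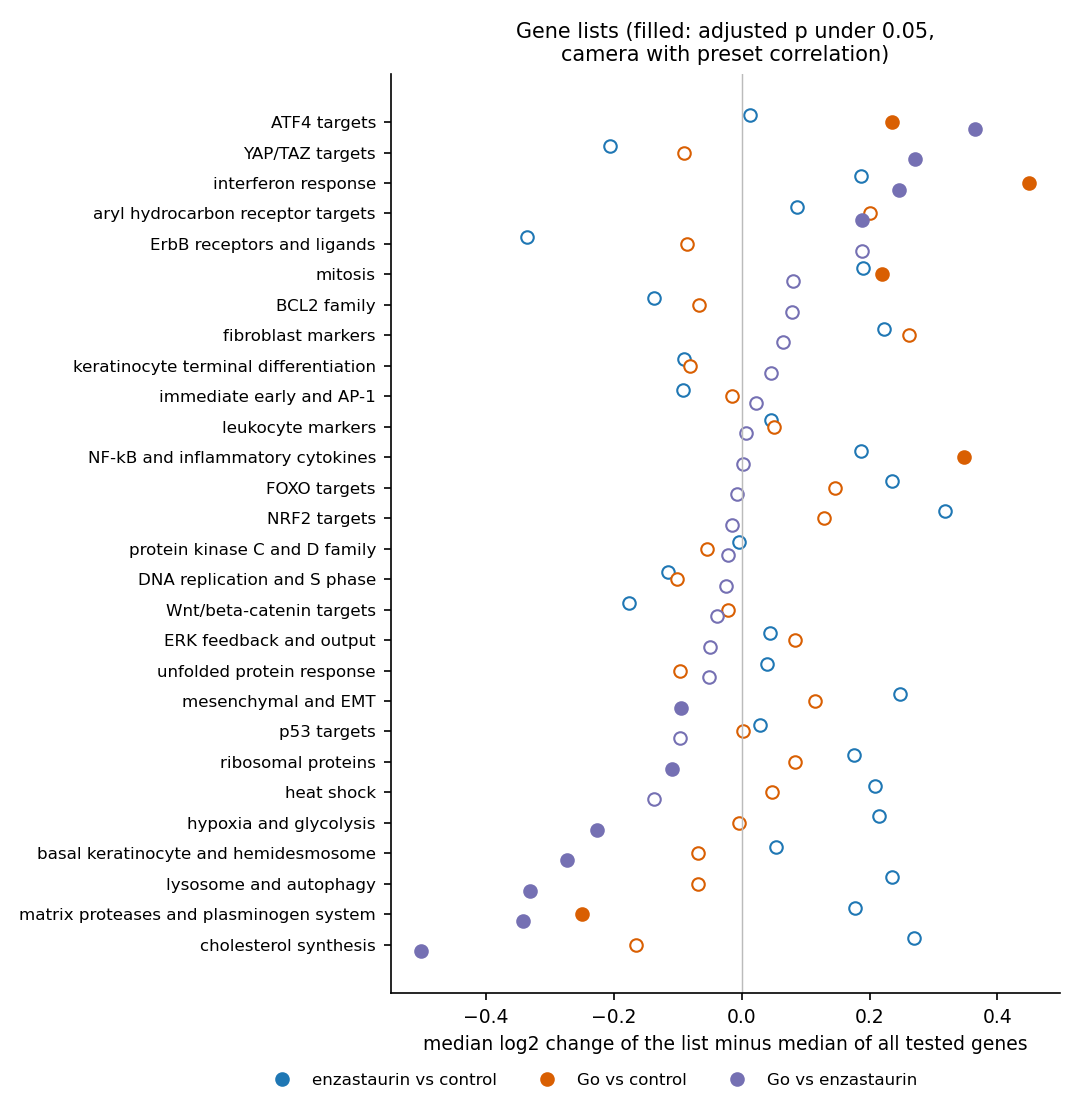
Median log2 change of each of 28 gene lists minus the median of all genes, for the 3 comparisons, with filled points where the camera test gave an adjusted p under 0.05. Between Go and enzastaurin 11 lists passed, led by cholesterol synthesis; 5 passed between Go and control and 0 between enzastaurin and control. With an estimated correlation 0 lists passed in each of the 3 comparisons.

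The comparison of enzastaurin with control asks which transcripts respond to that inhibitor. COL17A1, the hemidesmosomal collagen XVII, was higher in enzastaurin (n = 3) than in control (n = 3) by 1.39 (SE 0.098, limma adjusted p = 0.000147), GPNMB by 1.20 (SE 0.09, adjusted p = 0.000159), SQLE by 1.04 (SE 0.103, adjusted p = 0.000306) and MMP7 by 0.90 (SE 0.084, adjusted p = 0.000266). CCND1 was lower by -0.72 (SE 0.072, adjusted p = 0.000324), SLC3A2 by -0.70 (SE 0.072, adjusted p = 0.000331), and cyclin E1, CCNE1, decreased by 0.84 on the log2 scale (SE 0.085, adjusted p = 0.000324). These 7 genes also passed with the slide as a block, where their changes were 1.29, 1.21, 1.21, 1.04, -0.81, -0.63 and -0.77. In that block Go 1 and Go 2 alone set the slide difference. The block also keeps the difference of Go 1 from the controls. Across genes, that difference correlated at -0.692 with control 1 minus control 3. Passing in the block therefore does not exclude an array difference that also separates the controls. None of the 7 passed with each array's position along the difference between control 1 and control 3 as a covariate, where 10 genes passed in all. Their changes there were 1.16, 1.08, 1.04, 1.06, -0.74, -0.64 and -0.63. That position is computed from the values tested. It puts the controls at 1.087, 0.667 and 0.087 and enzastaurin between -0.408 and -0.473, so it nearly follows the treatment. A call lost with it is therefore not evidence against a change. Without the block 7096 of 12910 genes passed (2341 higher, 4755 lower), 55% of those tested, and 779 changed by at least 2-fold (404 higher, 375 lower).

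More of the named genes that passed with and without the block were the cyclooxygenase PTGS2 (0.75, SE 0.065), the co-chaperone BAG3 (1.15, SE 0.09), the sialidase NEU1 (0.67, SE 0.079), the AP-1 member JUNB (1.43, SE 0.141) and the interferon-induced GTPase MX1 (SE 0.155), which rose 1.62. Falling with and without the block were ARHGEF17 (-0.76, SE 0.073), the metalloprotease inhibitor TIMP2 (-0.72, SE 0.109) and the apoptosis effector BAX (SE 0.081), which fell by 0.56 on the log2 scale. Of 128 named genes called, 26 passed in the block. Among those that did not pass there, HMGCS1, which makes the precursor of mevalonate, changed by 0.73 (SE 0.083), MYC by -0.70 (SE 0.085), DUSP6 by -0.82 (SE 0.101), CXCL8, interleukin 8, by 3.32 (SE 0.599), CYP1B1 by 1.17 (SE 0.131) and the ErbB ligand NRG1 by -1.40 (SE 0.147). EGFR changed by -0.59 (SE 0.151, adjusted p = 0.0105), and by 0.09 in the block. CYP1A1, not above background on any enzastaurin array, did not pass (adjusted p = 0.848), and neither did VEGFA (0.07, SE 0.124, adjusted p = 0.632) or MKI67 (adjusted p = 0.0522, interval 0.03 to 0.40). VEGFA passed with the mean of its probes (1.03, adjusted p = 0.0183, in a range of 0.0183 to 0.985), and MKI67 without Go 1 or Go 2 (0.0481) or enzastaurin 3 (0.0329), in a range of 0.00808 to 0.586.

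Several of the largest rises were in genes named after pseudogenes or members of copy families, whose names are uncertain because a probe can bind the copies: NACA2 (6.23, SE 0.711), FTH1P12 (5.96, SE 0.657), PABPC3 (5.36, SE 0.416), TPT1P8 (4.35, SE 0.331) and the histone H4C2, at least 52.5-fold higher. In the block NACA2, FTH1P12, PABPC3 and TPT1P8 were higher by 2.96, 2.87, 4.30 and 2.86. GNG8, with the largest change of all, fell by 7.10 on the log2 scale (SE 0.981), PRDM10-DT by -5.83 (SE 0.742) and the kinase TNK2 decreased by 3.71 (SE 0.401). Over all alternatives the limma adjusted p ran from 4.83e-06 to 0.2 for GNG8 and from 7.65e-07 to 0.167 for H4C2, so these calls were not kept in every setting. Ribosomal protein genes had 8 rises, 1 fall and 19 not past among 28 (7 and 1 adjusted over the list alone), led by RPS23 (2.07, SE 0.228).

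No list passed in enzastaurin against control in the setting used. Camera gave 0 of 28 at an adjusted p under 0.05 and 9 at an unadjusted p under 0.05, while fry gave 20. With arrays scaled to the 75th percentile, the design's normalisation, camera gave 7 at an adjusted p under 0.05. Camera sets each list against the other genes, and the median of all genes was -0.14. Nearest were cholesterol synthesis (9 rose, 4 fell, 12 not past of 25; 9 and 3 adjusted over the list alone; adjusted p = 0.0525) and YAP and TAZ targets (1 rose, 13 fell, 5 not past of 19; the same adjusted over the list alone; median -0.34; adjusted p = 0.0525). Ribosomal proteins had an adjusted p of 0.0529. All lists had an adjusted p between 0.602 and 0.964 with an estimated correlation. At the preset correlation the values of 0.0525 and 0.0529 lie close to 0.05, and the calls moved with single arrays. Cholesterol synthesis and YAP and TAZ targets passed without control 1 (0.0259), control 2 (0.0327), enzastaurin 1 (0.0264), enzastaurin 3 (0.032), Go 1 (0.0392) or Go 2 (0.0392). Ribosomal proteins passed without enzastaurin 1 (0.0393), enzastaurin 3 (0.032), Go 1 (0.0392) or Go 2 (0.0392), hypoxia and glycolysis genes without control 2 (0.0327), and interferon response genes without enzastaurin 2 (0.0125). In all, cholesterol synthesis passed in 16 alternatives (0.00211 to 0.0498) and YAP and TAZ targets in 15 (0.000413 to 0.0498). With the slide as a block 5 lists passed, though few of their members did: cholesterol synthesis (1 rose and 0 fell there), NF-kB genes (4 and 0), interferon response genes (1 and 0), NRF2 targets (0 and 0) and ribosomal proteins (1 and 0). Without the block NF-kB genes had 9 rises and 6 falls of 27, interferon response genes 5 and 2 of 25, and NRF2 targets 8 and 4 of 19. YAP and TAZ targets had 0 rises and 2 falls in the block and did not pass there (adjusted p = 0.131), although their median was -0.37 there against -0.34 without it. With an estimated correlation in the same block 0 lists passed, and the adjusted p of these 5 was 0.688 to 0.728.

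In the other lists, calls went either way, and few members passed with the slide as a block. There DNA replication genes had 0 rises and 2 falls, ErbB genes 1 and 0, matrix proteases 2 and 2, mesenchymal genes 0 and 1, basal keratinocyte genes 1 and 0, ATF4 targets and p53 targets 0 and 1 each, and terminal differentiation genes, the protein kinase C and D family, fibroblast markers and leukocyte markers 0 and 0. Without the block, DNA replication genes had 4 rises, 17 falls and 14 not past among 35 (4 and 18 adjusted over the list alone), such as CCNE1 and MCM2 (-0.82, SE 0.101). ErbB receptors and ligands had 2 rises and 7 falls among 10 (3 and 7 adjusted over the list alone), with NRG1 and ERBB2 (-0.60, SE 0.096) among the falls, neither of them kept in the block (-1.06, SE 0.268, and -0.76, SE 0.183). Terminal differentiation genes had 3 rises and 10 falls among 25, including involucrin, IVL (-0.71, SE 0.118), also not kept (-0.83, SE 0.237). Matrix proteases had 8 rises and 5 falls among 18 (8 and 6 adjusted over the list alone), mesenchymal genes 6 and 4 among 13, and the protein kinase C and D family 2 and 5 among 12. PRKCA was 0.21 higher (SE 0.075, adjusted p = 0.0397), a difference of -0.007 with arrays scaled to the 75th percentile, and was not called without control 2 (0.129), control 3 (0.0766), enzastaurin 1 (0.0919), enzastaurin 2 (0.0668) or enzastaurin 3 (0.135), in a range of 0.0122 to 0.955. ATF4 targets had 2 rises and 9 falls among 24 with a median of -0.12, and p53 targets 4 and 8 among 20 with a median of -0.11, yet for either list camera's direction was up relative to other genes. Basal keratinocyte genes had 6 rises and 3 falls among 18, a median of -0.08 and a mean of 0.06. Of 5 fibroblast markers 2 rose and 2 fell (THY1 1.84, SE 0.411; LUM 0.55, SE 0.08; COL6A3, SE 0.118, fell by 0.67 on the log2 scale; DCN -0.33, SE 0.105), with an adjusted p of 0.504; DCN was not called without control 2, enzastaurin 1 or enzastaurin 2 (0.0956, 0.0803 and 0.0958). Of 6 leukocyte markers 1 rose and 2 fell (HLA-DRA 1.11, SE 0.145; CD3E -0.64, SE 0.098; TYROBP -0.26, SE 0.094), with an adjusted p of 0.926. TYROBP was not called without control 1 (0.0783), control 2 (0.154) or enzastaurin 1, 2 or 3 (0.0835, 0.114 and 0.105), and the ranges over all alternatives were 0.00564 to 0.854 for TYROBP and 0.002 to 0.974 for DCN.

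With the slide as a block 553 genes passed (208 higher, 345 lower), 420 of them among the 7096 with the same sign. Of 2418 called genes with more than 1 probe, 667 (27.6%) had each probe called the same way. The counts were 248 of 1470 (16.9%) between Go and control and 79 of 385 (20.5%) between Go and enzastaurin. Over all 24772 probes tested, 13033 passed between enzastaurin and control, 7349 between Go and control and 1108 between Go and enzastaurin. Where more probes pass, more of them pass together without any agreement within a gene, so these shares do not rank the comparisons. The share of calls that were higher was 33%, and 62% (3588 higher, 2195 lower) when arrays were scaled to their median, which moved the median of all genes from -0.14 to 0.06. Groups did not overlap in 68.9% of all genes, against 10% by chance.

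**Figure D5:**
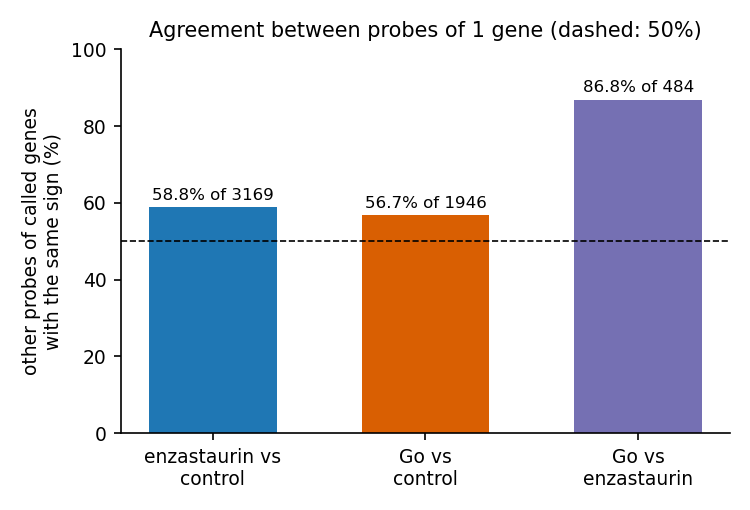
Percent of the other probes of called genes whose change had the same sign as that of the probe used, for enzastaurin against control, Go against control and Go against enzastaurin, with a dashed line at 50%. The shares were 58.8% of 3169 probes, 56.7% of 1946 and 86.8% of 484.

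The comparison of Go with control asks the same of the second inhibitor. CYP1A1 was higher in Go (n = 2) than in control (n = 3; limma adjusted p = 0.00111), and CYP1B1, another target of the aryl hydrocarbon receptor, was higher by 1.68 (SE 0.147, adjusted p = 0.00221, 95% interval 1.34 to 2.01). The size is not given for CYP1A1, because its control mean of 7.86 was no higher than the enzastaurin mean of 7.89, which was not above background. Among interferon response genes, of which 10 of 25 rose, HERC5 was higher by 1.31 (SE 0.129), RSAD2, viperin, by 1.18 (SE 0.175) and MX1 by 1.57 (SE 0.174). MMP1 fell by 1.17 on the log2 scale (SE 0.14, adjusted p = 0.00384) and MMP7 by -0.65 (SE 0.093, adjusted p = 0.00544). In all 4097 genes passed (1497 higher, 2600 lower), 31.7% of those tested, and 477 changed by at least 2-fold (271 higher, 206 lower). With each array's position along the difference between control 1 and control 3 as a covariate only 2 genes passed. None of the genes named above did: CYP1B1 was higher by 1.23, HERC5 by 1.08, RSAD2 by 0.83 and MX1 by 1.43, and MMP1 and MMP7 differed by -0.74 and -0.52. Go lies at -0.189 and -0.337 on that axis, below every control, so here too a lost call is not evidence against a change.

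Interferon response genes had 10 rises, 0 falls and 15 not past among 25 (12 rises adjusted over the list alone), with a median of 0.35 and an adjusted p of 5.78e-07 (adjusted p = 0.522 with an estimated correlation). ATF4 targets had 7 rises, 0 falls and 17 not past among 24 (6 rises adjusted over the list alone), including ATF3 (0.87, SE 0.1), CTH, cystathionine gamma-lyase (0.83, SE 0.116), ASNS (0.67, SE 0.083) and the serine synthesis enzyme PSAT1 (0.58, SE 0.084). Their adjusted p was 0.00222 (adjusted p = 0.522 with an estimated correlation), 0.313 without Go 1 and 3.17e-06 to 0.313 over the alternatives with the preset correlation. NF-kB genes had 11 rises, 4 falls and 12 not past among 27, the same adjusted over the list alone, such as the chemokine CCL20 (SE 0.231), which rose 1.29. Their adjusted p was 0.00986 (adjusted p = 0.522 with an estimated correlation), 0.349 without Go 1, with a range of 0.000201 to 0.349. Matrix proteases had 10 falls, 0 rises and 8 not past among 18, the same adjusted over the list alone, with MMP1 and MMP7 among the falls. Their adjusted p was 0.0171 (adjusted p = 0.522 with an estimated correlation), 0.185 without Go 1, with a range of 0.00148 to 0.185. Mitosis genes had 4 rises, 4 falls and 24 not past among 32, the same adjusted over the list alone, with ANLN, anillin, at 1.03 (SE 0.178). Their adjusted p was 0.0425 (adjusted p = 0.691 with an estimated correlation), 0.39 without Go 1, 0.0635 without control 1 and 0.0581 without control 2, with a range of 0.00103 to 0.462.

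With the slide as a block the calls were 4 rises among interferon genes, 5 among ATF4 targets, 6 rises and 2 falls among NF-kB genes, 2 falls among matrix proteases and 2 rises among mitosis genes. Without it, cholesterol synthesis genes had 1 rise, 10 falls and 14 not past among 25 (1 and 12 adjusted over the list alone), with a median of -0.27 and an adjusted p of 0.0954. The list passed in 5 alternatives (0.00339 to 0.042): with the slide as a block (0.019), without Go 2 (0.019), without control 1 (0.042), without the filter on dim probes (0.0306) and with the position along the control difference as a covariate (0.00339). With an estimated correlation its adjusted p was 0.522, and 0.591 in the block. The falls included the isomerase IDI1 (-0.87, SE 0.149) and MSMO1, at least 1.61-fold lower. DNA replication genes had 1 rise and 14 falls among 35, the same adjusted over the list alone (adjusted p = 0.179, and 0.00339 with that covariate, the only alternative in which it passed), such as the clamp loader subunit RFC3 (-0.68, SE 0.113). Aryl hydrocarbon receptor targets had 3 rises and 2 falls among 9, the same adjusted over the list alone (adjusted p = 0.231), CYP1A2 falling (-1.24, SE 0.229) where CYP1A1 and CYP1B1 rose. The protein kinase C and D family had 1 rise and 3 falls among 12 (adjusted p = 0.537). COL17A1 rose by 0.89 (SE 0.11), BAG3 by 0.91 (SE 0.1), JUNB by 0.98 (SE 0.158) and tissue factor, F3, by 0.93 (SE 0.125), while SPRR1A (-0.91, SE 0.162), the antiproliferative gene BTG2 (-0.78, SE 0.134), JUN (-0.60, SE 0.106) and BAX (-0.61, SE 0.091) fell. CCND1 (-0.10, interval -0.29 to 0.08, adjusted p = 0.338), PRKCA (-0.10, adjusted p = 0.376), MKI67 (0.12, adjusted p = 0.328), EGFR (adjusted p = 0.161, interval -0.71 to 0.06) and VEGFA (adjusted p = 0.108), which was lower in Go, did not pass. VEGFA passed in the opposite direction with the mean of its probes (1.49, adjusted p = 0.0162), and as lower without Go 1 (-0.55, 0.0109), in a range of 0.0109 to 0.838; EGFR passed without Go 1 (-0.66, 0.00274), in a range of 0.00274 to 0.935. IVL was lower by -0.57 (SE 0.132, adjusted p = 0.0173), a call lost without control 2 (0.0552) and without Go 2 (0.0623), in a range of 0.00384 to 0.579. Of 5 fibroblast markers 1 rose and 1 fell (THY1 and COL6A3, adjusted p = 0.537 for the list), and of 6 leukocyte markers 1 fell (CD3E, adjusted p = 0.973 for the list). The calls of THY1, COL6A3 and CD3E were lost without Go 2 (0.104, 0.19 and 0.163) and without control 2 (0.0573, 0.0998 and 0.0818), and those of COL6A3 and CD3E without control 1 (0.0849 and 0.0711). COL6A3 was not called without enzastaurin 1, 2 or 3 either (0.0551, 0.0523 and 0.0535). The ranges were 0.0022 to 0.739 for THY1, 0.00532 to 0.782 for COL6A3 and 0.00961 to 0.626 for CD3E.

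With the slide as a block, which is Go 1 alone against the controls, the same fit as without Go 2, 824 genes passed (445 higher, 379 lower), 718 of them among the 4097, the lone array being assumed to vary like those of the other groups; the count was 1978 without control 1 and 948 without control 2, and 39 of 113 named calls were kept in every such fit. The share of calls that were higher was 36.5%, and 69.2% (1640 higher, 730 lower) with arrays scaled to their median; groups did not overlap in 57.4% of all genes, against 20% by chance.

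The responses to the 2 inhibitors can be set side by side against the shared controls. Genes called higher with each inhibitor numbered 1254, with 271.5 expected of independent lists, genes called lower with each 2048 (957.6 expected), and 49 went in opposite directions. MX1, COL17A1, BAG3, JUNB and CYP1B1 rose with each, and BAX and BTG2 fell with each. MMP7 went apart: it rose with enzastaurin (0.90) and fell with Go (-0.65), and the difference itself passed (-1.55, adjusted p = 0.000298). CYP1A1 rose with Go alone, and was at least 3.26-fold higher than with enzastaurin. CCND1 fell with enzastaurin alone, and the difference was 0.61 (95% interval 0.43 to 0.80). Across genes, which are not independent replicates, the log2 changes correlated at r = 0.874 with a covariance of 0.2312, against 0.446 and 0.0105 in 50 simulations without effects. The 3 controls cannot be split into parts of at least 2 arrays, so part of the excess may come from the shared controls. The simulated noise was independent for each gene and array and held no slide difference. Go 2 shares its slide with every enzastaurin array and with no control, so part of the excess may also come from the slide. With the slide as a block 296 genes went the same way and 4 in opposite directions, but there each comparison holds the same difference of Go 1 from the controls, so part of that overlap is built in. The number called the same way with each inhibitor, 3302 in all, was 1577 without control 1, 791 without control 2, 2132 without enzastaurin 1, 2178 without enzastaurin 2 and 670 without Go 2. It was 294 when each comparison was fitted with only its own groups, and 1 with the position along the control difference as a covariate. That covariate separates every control from every treated array, so the drop to 1 does not show that the responses lack overlap.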

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

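The tests on the difference among controls, gradients along the slide, the other probes of a gene, probes without a gene name and the control covariate were chosen after the results were seen, and the test of a gradient shared by the slides was first run on the genes called and then on all genes, since the comparison had picked the genes called; those on splits, pseudogenes and a slide cause of the Go differences were chosen before, although the enzastaurin medians of the pseudogenes had been seen.

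Signals outside the genes tested were of 2 kinds. Spike-in control spots, which hold no cellular RNA, lay above the level of the control arrays on Go 2, by a median of 0.48 log2 units with 9 of 10 spike-in probes above every control; on Go 1 the median was 0.09, with 7 of 10 above every control. This item was first set up for enzastaurin minus control, which gave 0.02, and Go 2 was chosen after its value was seen. Probes without a gene name also differed: 3372 of 6186 (54.5%, 1776 of them higher) passed between enzastaurin and control, 1945 (31.4%) between Go and control and 155 (2.51%) between Go and enzastaurin. Of all 24772 probes in the same fit 13033, 7349 and 1108 passed. The shares against control thus lie near those of all probes and show nothing particular to probes without a name. Groups of 3 or fewer arrays were not searched for an array standing apart.

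The large number of calls between enzastaurin and control (7096) was weighed first. Across genes, which are not independent replicates, the difference of control 1 from control 3 correlated at -0.623 with that of enzastaurin from control 2, so an array difference that also separates the controls may account for many of the calls. Altered mRNA levels as the whole cause are argued against by the other probes of the genes called, of which 58.8% of 3169 moved the same way, against 56.7% of 1946 between Go and control and 86.8% of 484 between Go and enzastaurin. A gradient with array position that the slides share is argued against as the whole cause, since over all genes tested control and enzastaurin arrays at the same position differed by an rms of 0.616 and 0.478, against at most 0.351 within a group; a gradient that adds to the calls stays open (r = 0.141 between the differences of array 1 from array 3 in the control and enzastaurin groups, between the values set for its presence and absence). The 10 splits of the 6 arrays are too few for a share under 0.05: 1 of 10 gave as many genes (7784 in the real split, fitted without Go, at most 0 in the others), and 5 of 10 as many lists (3 in the real split, at most 7 in the others).

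Genes annotated as pseudogenes rose with enzastaurin, 12 of 21 with 1 falling, at a median of 0.75 against -0.14 for protein coding genes, and were weighed next. The larger class of 124 transcribed pseudogenes did not follow: its medians were -0.05 for enzastaurin minus control (32 rose, 35 fell) and -0.04 for control 3 minus control 1. For the 21, the median difference of control 3 from control 1 exceeded that of protein coding genes by 0.454 (permutation p = 1e-04, the smallest that 10000 permutations can give). The test permuted genes, which are not independent replicates, over a difference of single arrays. Its p-value therefore does not measure the spread between arrays. Across all genes the difference of control 1 from control 3 correlated at -0.636 with that of enzastaurin from control, which shares those arrays. Genes higher in enzastaurin thus tended to be higher in control 3 than in control 1, so the 0.454 is not separate evidence about pseudogenes. The prediction for a response to the inhibitors as the whole cause did not allow the 0.454, since these control arrays received no inhibitor. But the 0.454 goes with a difference seen across all genes, between single arrays, in a class whose enzastaurin medians had been seen. It therefore cannot decide on a response. Binding of transcripts from near-identical genes to these probes, changing from array to array, is a candidate explanation and stays open; no probe sequence was compared here.

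The calls between Go and control (4097) were not weighed on their own. Across genes, the difference of control 1 from control 3 correlated at -0.665 with that of Go from control, which shares those arrays. For Go 1 minus the controls, on a single slide, the correlation was -0.692. An array difference that also separates the controls may thus account for many of these calls too. The calls between Go and enzastaurin (1054) were weighed last. With the position along the control difference as a covariate 1045 of 1054 (99.1%) kept their call. Go lies at -0.189 and -0.337 on that axis and enzastaurin between -0.408 and -0.473, so the covariate could remove few calls. The calls kept therefore cannot decide on that difference as the whole cause, and Go 1 lies between control 3 (0.087) and enzastaurin on the axis. Across genes, Go minus enzastaurin correlated at 0.215 with the difference of control 1 from control 3, against -0.636 for enzastaurin minus control. The slide as the whole cause is argued against by genes called from Go 1 and enzastaurin 1 and 2, of which 76.6% of 992 moved the same way from enzastaurin 3 to Go 2, on a single slide. In that call Go 1 stood alone for its group, so the spread came from the control and enzastaurin arrays, and the check set 1 array against 1. A difference in response to the inhibitors may thus underlie much of this comparison, as a hypothesis, with the unstated dose of Go and the spike-in difference of Go 2 left open.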

How the results depend on the processing

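The slide block for lists and overlap, lists with no filter, with all 8 arrays above background, with the authors' value table, with the mean of all probes or with an intensity trend, the overlap in those settings, with only the groups compared or with array weights, the scalings, plain background subtraction, pixel medians, spots not found, tests within a slide and the control covariate were chosen after the results were seen. Over all alternatives named genes kept their direction and side of the threshold 6442 times. They lost the call 1131 times, gained it 28 times and turned 17 times. A gene called in neither setting counted as kept whatever its direction. Lists did so 298, 38, 68 and 0 times, counting only lists that passed in the setting used or the alternative. Some uncounted lists turned with the slide block, such as NF-kB genes between Go and enzastaurin and YAP and TAZ targets between Go and control. Where a value moved, the cause was not tested, except that a fold threshold lowers counts by construction. Signal over background limits the tests to genes above it on at least 2 arrays.

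Genes called between enzastaurin and control (7096) were 553 with the slide block, 10 with the control covariate and 779 at 2-fold, and 5396 (without control 2) to 7784 (without Go 1 or Go 2) with an array left out. Between Go and control (4097) they were 329 with only the groups compared, 1542 with array weights, 824 with the slide block, 2370 scaled to the median, 2 with the control covariate, 477 at 2-fold and 66 within a slide (42 shared), and 824 (without Go 2, the same fit as the slide block) to 5578 (without control 3) with an array left out. Between Go and enzastaurin (1054) they were 52 at 2-fold and 3240 within a slide (1024 shared), and 246 to 1706 with an array left out. Within a slide a single Go array is set against 3 arrays of the other group, so for 66 and 3240 the spread comes from that group alone: pairs of controls differed by an rms of 0.201 to 0.351 and pairs of enzastaurin arrays by 0.119 to 0.162. The overlap (3302) was 294 with only the groups compared, 1390 with array weights, 296 with the slide block, 2035 scaled to the median and 1 with the control covariate, and 670 to 4662 (without control 3) with an array left out. The control covariate separates every control from every treated array, so calls lost with it against control are not evidence against a change. With the replicate block the counts were 6986, 4555 and 528, the overlap 3668 and the lists 0, 5 and 10. Deviations of same-numbered samples from their group means correlated across genes, which are not independent replicates, at 0.084, 0.012 and 0.151 (control and enzastaurin). The values were 0.111 and -0.145 (control and Go) and 0.066 and 0.094 (enzastaurin and Go). With 2 Go arrays the deviation of each is the exact negative of the other's, and groups of 3 leave little freedom. These correlations therefore cannot decide whether the numbers pair the samples.

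Lists past the threshold between enzastaurin and control (0) were 3 with no filter, with all 8 arrays above background, with the authors' value table, with pixel medians and with the control covariate, 4 with the mean of all probes, 5 with the slide block, 7 scaled to the 75th percentile, 5 to the median, 2 without spots not found and 20 with fry. They were 0 with an estimated correlation or plain background subtraction. With an array left out they were 0 (without control 3) to 3: 2 without control 1, 3 without control 2, 3, 1 and 3 without enzastaurin 1, 2 and 3, and 3 without Go 1 or Go 2. Between Go and control (5) they were 0 with an estimated correlation and 14 with fry, and 1 (without Go 1) to 6 (without Go 2). Between Go and enzastaurin (11) they were 7 with the slide block, 0 with an estimated correlation and 7 (without Go 1) to 13 (without enzastaurin 1) with an array left out.

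Directions of named genes called in the setting used or in the alternative turned as follows. Between Go and control with the mean of all probes: FEN1 0.10, FTL -0.066, ME1 0.17, CTSB 0.17 and VEGFA 1.49, which passed there. Between enzastaurin and control with the slide block: PHLDA3 -0.18, EGFR 0.086, CHAC1 0.002 and TXNIP 0.40; scaled to the 75th percentile: PRKCA -0.007; with the control covariate: UBE2C -0.37, CDK1 -0.01, A2ML1 0.025, CDH3 -0.15, IL1B -0.26 and THY1 -0.19. Between Go and control with the control covariate: BID -0.087.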

Other observations

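List tests with the slide block, with median scaling and with the mean of a gene's probes were chosen after the results were seen. Those with arrays scaled to the 75th percentile, the design's normalisation, were run after that too. Genes of smaller groups in Go against control, which the text has not yet described, went as follows: of 14 BCL2 family genes 1 rose and 5 fell (adjusted p = 0.537 by camera), among them HRK, a BH3-only member (-1.71, SE 0.297; adjusted p = 0.0539 by limma without Go 2, in a range of 0.000607 to 0.358). Of 13 FOXO targets 2 rose and 0 fell (adjusted p = 0.225), CDKN1B, the cell cycle inhibitor p27 (0.62, SE 0.132), and CCNG2 (SE 0.104), which rose 0.51. By limma CDKN1B was not called without control 2 (0.0547), nor CCNG2 without control 2 (0.0501) or Go 2 (0.0543), with ranges of 0.00457 to 0.459 and 0.00654 to 0.203. Of 20 p53 targets 1 rose and 6 fell (1 and 7 adjusted over the list alone; adjusted p = 0.625), including BTG2 (-0.78, SE 0.134). Of 14 unfolded protein response genes 1 rose and 4 fell (adjusted p = 0.605).

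In enzastaurin against control, of 14 BCL2 family genes 1 rose and 6 fell (2 and 7 adjusted over the list alone; adjusted p = 0.353 by camera), HRK at -2.24 (SE 0.265) and BBC3 at -0.69 (SE 0.103), neither of them kept with the slide as a block (-1.56, SE 0.479, and -0.31, SE 0.135). There 0 rose and 1 fell, at a list median of -0.40 against -0.27 without the block. Of 22 hypoxia and glycolysis genes 7 rose and 2 fell (adjusted p = 0.108), with LDHA, lactate dehydrogenase A, at 0.77 (SE 0.149) and EGLN3 at 1.03 (SE 0.146), and with the slide as a block 0 rose and 0 fell (LDHA 0.63, SE 0.303; EGLN3 0.88, SE 0.297). This list passed in 2 alternatives, without control 2 (0.0327) and with arrays scaled to the 75th percentile (0.0448). Of 23 lysosome and autophagy genes 6 rose and 4 fell (6 and 1 adjusted over the list alone; adjusted p = 0.108), with the autophagy receptor SQSTM1 at 0.59 (SE 0.09) and the protease CTSL at 0.53 (SE 0.09), neither of them kept in the block (0.45, SE 0.171, and 0.69, SE 0.169), where 2 rose and 2 fell at a list median of 0.16 against 0.10 without it. This list passed in 3 alternatives (0.0253 to 0.0417), with the mean of a gene's probes and with arrays scaled to the median or the 75th percentile. With an estimated correlation the adjusted p was 0.777 for the BCL2 family and 0.602 for each of the other 2 lists.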
